A study of Mus musculus with 12 samples.

How the data were processed

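RNA of primary mouse hepatocytes was measured on 12 Affymetrix mouse expression arrays holding 45101 probe sets, 3 arrays in each of 4 groups (wild type or human AHR, vehicle or 10 nM TCDD for 6 h). Per the submitters' processing notes and the design text, the authors preprocessed the scans with GCOS, normalised the deposited intensities with PLIER-MM in Affymetrix Expression Console 1.1, and compared groups with SAM. The design text gives 1 array per mouse. The probe annotation used by the submitters is not given in the sources used here. The deposited values were linear and never negative. After trimming 2% at each end, the mean over all probe sets was 150 in 9 arrays and 500 in the 3 wild type TCDD arrays. Such a shared round mean is what global scaling of each array gives and not what PLIER gives, so the named algorithm and the values are at odds. Left as deposited, the 3 arrays would lie 3.333 times, or 1.74 on the log2 scale, above the others. Every array was therefore rescaled to a trimmed mean of 150.

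Values were taken as log2 of the rescaled intensity plus 16. The annotation listed 35877 of the 45037 probe sets left after removing 64 control probe sets. Of these, 34945 named 1 gene symbol and 932 named several. A gene was represented by the probe set with the highest mean over all 12 arrays among those with its symbol alone, which gave 18194 genes. limma 3.58.1 in R 4.3.3 fitted a mean per group over all 12 arrays (8 residual degrees of freedom) with eBayes and an intensity trend. Tests were two-sided, and p values were adjusted with Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05 and 95% confidence intervals. Folds are 2 to the power of the log2 change, so they include the offset of 16, while signals are means of the rescaled intensities without it. The comparisons were TCDD against vehicle in each genotype, the difference of these effects, the genotypes under vehicle, and the overlap of the TCDD calls (Fisher exact test, one-sided).

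Of 31 gene lists, 30 were tested with camera at a preset correlation of 0.01, and their p values were adjusted over the lists of a comparison. They held 670 entries, of which 599 (89.4%) were measured. Each list test was repeated with the correlation estimated per list and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. For list members, p values were also adjusted over the list alone. Named genes followed a rule. In each comparison these were the 10 largest called changes in either direction among genes whose groups did not overlap, all measured AHR targets for the TCDD comparisons, Ahr, Arnt, Ttr and Alb, and up to 4 members of each described list with the smallest p. The lists, the comparisons, the tests, this rule and most alternatives were chosen before the data were examined. The rescaling was the step that the values themselves called for.

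Alternatives covered the offset (none or 50), quantile normalization, a shared median, leaving out the dimmest 40% of genes, the fit (no trend, array weights, only the 6 arrays of a comparison), the handling of probe sets, a replicate term, fold limits of 1.5 and 2, SAM over all 20 relabellings at a false discovery rate of 5%, and leaving out each array in turn. After the data had been seen, a rescaling to 500, the removal of both wild type replicate 2 arrays, list tests with the replicate term inside each genotype, and comparisons averaged over genotypes or treatments, with their fits by same-numbered arrays, were added. The fit was tested on simulated data with 100 genes planted at each size among 18194. At a planted log2 change of 1 it recovered 59% of genes for TCDD in wild type, 57% in human AHR cells and 27% for the difference, and at 2 it recovered 100%, 98% and 94%. The simulated noise was drawn independently for each gene and array, without structure shared by arrays. With this many planted changes the adjusted threshold is also easier to pass than where few genes change. These shares are therefore not the sensitivity of the real comparisons. The main fit held no replicate term, so its counts, list calls and adjusted p values left any pairing out. In alternative and added fits, same-numbered vehicle and TCDD arrays of human AHR cells were taken as paired. Their deviations from the group means correlated across genes with r from 0.19 to 0.27, against at most -0.04 between other numbers. This pairing comes from the values and not from the design text. Array quality was checked with medians, correlations and 3′ to 5′ ratios, and 0 pairs of arrays were identical. Probe sets without a listed symbol (9160) were not analysed here by gene, and neither were the raw scans. The labels give no scan dates or culture days, so genotype and day of culture cannot be told apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.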

Results

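Gene expression was measured on 12 Affymetrix mouse expression arrays, each hybridised with RNA of primary hepatocytes kept in culture for 48 h and then given vehicle (DMSO) or 10 nM TCDD for 6 h. TCDD is a dioxin that binds and activates the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. Per the labels, 6 arrays came from C57BL6/J mice, which carry the mouse receptor (wild type). The other 6 came from mice with a floxed Ahr gene, an Alb-cre transgene and human AHR under the Ttr promoter (human AHR). Each genotype had 3 vehicle and 3 TCDD arrays, and the design text gives 1 array per mouse. After rescaling, array medians lay between 16.5 and 23.5, and correlations across genes between arrays of a group lay between 0.957 and 0.982. The group means of the Gapdh 3′ to 5′ signal ratio, a measure of RNA integrity, ran from 0.808 in wild type vehicle to 0.834 in human AHR vehicle arrays, and each human AHR vehicle array lay above each wild type vehicle array. The Actb ratio averaged 1.39 and 1.49 in these groups. Arrays give no counts, and the number of arrays limits the precision.

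Ahr itself had a mean signal of 374 ± 210 (SD, n = 3) in wild type vehicle arrays and 217 ± 22.2 in human AHR vehicle arrays. The log2 difference was -0.62 (standard error 0.31, limma adjusted p = 0.965), with human AHR lower in 3 of 3 arrays. Whether this probe set lies in the deleted part of the gene is not given in the sources used here, so its signal does not test the deletion, and the human transcript was not analysed here. Arnt, which encodes the partner of the receptor, differed by -0.24 (standard error 0.21, adjusted p = 0.965). Ttr, whose promoter drives the human transgene, had a signal of 12690 ± 1618 in wild type and 13940 ± 1501 in human AHR vehicle arrays, a log2 difference of 0.14 (adjusted p = 0.966). Alb, the main secreted product of hepatocytes, differed by 0.12 (adjusted p = 0.974). Xist, the transcript that silences an X chromosome in female cells, stood at 3085 in wild type vehicle replicate 2 and at 2952 in wild type TCDD replicate 2, and at no more than 29.3 in the other arrays. Eif2s3y, a Y-linked gene, read 4.7 and 0.42 in those arrays and at least 452.7 in the others. This is the pattern of female cells in the wild type replicate 2 arrays and of male cells in the others. Sex was therefore not balanced between the genotypes, and it was not a term of the fit.

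The question of the first comparison is what TCDD does through the mouse receptor. In wild type hepatocytes, Tiparp, an AHR-induced ADP-ribosyltransferase, rose 2.47-fold with TCDD, from 1137 ± 248 to 2811 ± 445 (SD, n = 3). Its log2 change was 1.30 (standard error 0.15, 95% confidence interval 0.97 to 1.64, adjusted p = 0.0192), higher in 3 of 3 arrays. Among the 19 measured members of the list of AHR target genes, 16 lay above vehicle, with a median log2 change of 0.41, and the list rose as a group (camera adjusted p = 7.92e-06, and adjusted p = 0.0251 with an estimated correlation). Of these members, 1 passed over all genes and 5 passed when adjusted over the list alone. These were Tiparp, Cyp1a1 and Cyp1a2, which encode cytochromes P450 that metabolise aromatic compounds, Pmm1, a phosphomannomutase, and Xdh, the xanthine dehydrogenase of purine breakdown. Cyp1a1 averaged 22.6 ± 3.61 under vehicle and 902.6 ± 1399 under TCDD, with single arrays at 124.9, 2518 and 64.89. Its log2 change was 3.00 (95% confidence interval 1.11 to 4.88, adjusted p = 0.966, and 0.0276 adjusted over the list alone). Cyp1a2 went from 591 ± 154 to 1150 ± 567 (log2 0.87, adjusted p = 0.966, and 0.0317 adjusted over the list alone).

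Beyond the AHR targets, 4 lists were called by camera in wild type cells, and 0 of their members passed, over all genes or adjusted over the list alone. Genes of cholesterol synthesis fell together, with 18 of 20 measured members below vehicle and a median of -0.26 (adjusted p = 6.25e-05, and adjusted p = 0.707 with an estimated correlation). Dhcr7, which makes the last step of the pathway, stood at -0.70, Hmgcs1, an early enzyme, at -0.65, and Fdps, the farnesyl diphosphate synthase, at -0.75. With 1 array left out the list stayed called, at adjusted p up to 0.0436 (without wild type vehicle replicate 2), while Dhcr7 lay between -0.98 and -0.32, Hmgcs1 between -1.04 and -0.29 and Fdps between -1.14 and -0.45. Interferon-stimulated genes fell together, with 20 of 22 members lower and a median of -0.31 (adjusted p = 0.000447, and adjusted p = 0.707 with an estimated correlation), among them Oasl2 at -0.71 and Oas1a at -0.43, sensors of viral RNA. That call ended without wild type vehicle replicate 2 (adjusted p = 0.103) and turned direction without wild type TCDD replicate 3 (adjusted p = 0.97). Genes of the unfolded protein response rose, with 23 of 24 members higher and a median of 0.25 (adjusted p = 0.00208, and adjusted p = 0.742 with an estimated correlation), among them the transcription factors Atf4 at 0.43 and Atf3 at 0.62. Without wild type TCDD replicate 3 this list had the opposite direction (adjusted p = 0.72). Oxidative phosphorylation was lower in 17 of 24 members with a median of -0.05 (adjusted p = 0.04996, and adjusted p = 0.707 with an estimated correlation). With arrays shifted to the same median, 0 of its members were positive and the median was -0.17, while that of the unfolded protein response was 0.14. The median of all genes moved from 0.03 to -0.09 with that shift. Among the fits that left out 1 array, the oxidative phosphorylation call stood without wild type vehicle replicate 1 or wild type TCDD replicate 3. It ended without wild type vehicle replicate 3 (adjusted p = 0.359) or wild type TCDD replicate 1 (0.614) or 2 (0.101). It also ended with wild type vehicle replicate 2 or any single human AHR array left out (0.0514 to 0.0604). The same held with no offset (0.0683), a rescaling to 500 (0.0596) or both Xist-high arrays left out (0.0834).

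Over all 18194 genes, limma called 1 gene in wild type cells, Tiparp, and 761 genes had an unadjusted p under 0.05, against 909.7 expected by chance. In 1120 genes all TCDD arrays lay above all vehicle arrays and in 513 below, 9% of the genes against 10% by chance. Among the fits that left out 1 array, the Tiparp call stood without wild type vehicle replicate 1 or wild type TCDD replicate 3. It ended with any single human AHR array left out (adjusted p from 0.0572 to 0.0633). It ended as well without wild type vehicle replicate 2 (0.097) or 3 (0.197), or wild type TCDD replicate 1 (0.0902) or 2 (0.0729). The call also ended without both Xist-high arrays (0.145), with log2 values from 1.03 to 1.47 over all settings. It also ended without the intensity trend (0.102), with arrays shifted to the same median (0.0642) and from its 6 arrays alone (0.986). The deposited wild type TCDD arrays were scaled differently from the other 9, so in this genotype the treatment and the deposited scaling coincide.

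**Figure D1:**
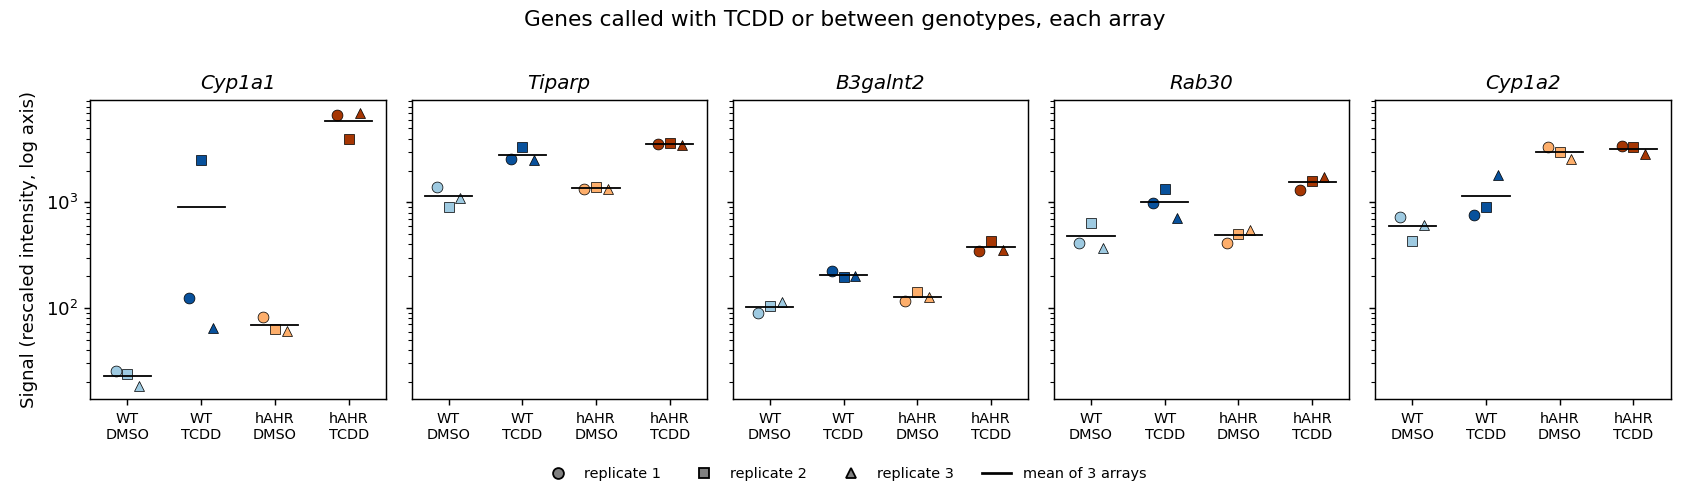
Signal (rescaled intensity, log axis) of Cyp1a1, Tiparp, B3galnt2, Rab30 and Cyp1a2 in the 4 groups of wild type (WT) and human AHR (hAHR) arrays, with a symbol per array and a line at the mean of 3 arrays. Cyp1a1 under TCDD averaged 902.6 in wild type, with arrays from 64.89 to 2518, and 5856 in human AHR.

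The second comparison asks what TCDD does through the human receptor in mouse hepatocytes. In human AHR arrays, Cyp1a1 rose 68.0-fold on the fitted scale, from 68.5 ± 11.7 to 5856 ± 1611 (SD, n = 3; log2 6.09, standard error 0.87, adjusted p = 0.0424). Rab30, a small GTPase of the Golgi, rose 3.09-fold, from 487 ± 68.7 to 1541 ± 213 (log2 1.63, standard error 0.23, adjusted p = 0.0424). B3galnt2, a glycosyltransferase that acts on dystroglycan, rose 2.72-fold, from 128 ± 12.0 to 376 ± 48.4 (log2 1.44, standard error 0.15, adjusted p = 0.00537). Tiparp rose 2.59-fold, from 1357 ± 40.4 to 3542 ± 65.3 (log2 1.37, standard error 0.15, adjusted p = 0.00537). Each of these genes was higher in 3 of 3 TCDD arrays. The dimmer probe sets of B3galnt2 gave 1.38, 0.425 and 0.261, that of Rab30 gave 0.551, and with the mean over probe sets B3galnt2 (adjusted p = 0.524) and Rab30 (adjusted p = 0.843) were not called. Cyp1a2 was at 2975 ± 391 under vehicle and 3207 ± 313 under TCDD (log2 0.11, adjusted p = 1).

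In human AHR arrays the AHR target list rose, with 15 of 19 members above vehicle and a median of 0.30 (camera adjusted p = 4.08e-10, and adjusted p = 0.00408 with an estimated correlation). Of the list, 2 genes passed over all genes and 2 adjusted over the list alone, Cyp1a1 and Tiparp in each case. Nfe2l2, which encodes the antioxidant regulator NRF2, stood at 0.60 (0.0708 adjusted over the list alone), Nqo1, a quinone reductase, at 0.62 (0.0769), and Cyp1b1, a further cytochrome of the family, at 1.03 (0.0708) on a vehicle signal of 3.2, with values from 0.37 to 2.48 over the settings. Interferon-stimulated genes fell together, 20 of 22 lower with a median of -0.21 (adjusted p = 0.0107, and adjusted p = 0.992 with an estimated correlation), with Mx2 at -0.69 and Ifit3 at -0.56, antiviral proteins. That call ended without human AHR vehicle replicate 2 (adjusted p = 0.173) or TCDD replicate 2 (0.108). Ribosomal protein genes rose with a median of 0.10 (14 of 15 higher), proteasome genes with 0.07 (23 of 25) and oxidative phosphorylation genes with 0.07 (22 of 24), each at adjusted p = 0.0418, and each at adjusted p = 0.992 with an estimated correlation. Examples were Rpl6 at 0.14, Psmd1 at 0.17 and Ndufb8 at 0.16. After quantile normalization the medians of these lists were 0.05, 0.03 and 0.03. In these lists 0 members passed, over all genes or adjusted over the list alone. Outside the called lists, Reln (0.88) and Acta2 (-1.15), a secreted protein and a smooth muscle actin that mark stellate cells, passed when adjusted over the list alone (0.0426 each), while their list of stellate and fibroblast markers was not called (adjusted p = 0.926). Their dimmer probe sets did not follow, at -0.10 for Reln and at 0.14 and -0.13 for Acta2. NRF2 targets were not called (adjusted p = 0.140). With the same-numbered arrays paired, as a replicate block within genotype, they stood at adjusted p = 0.0366, and at adjusted p = 0.855 with an estimated correlation and 0.95 with fry in that fit. In the fit with the block the AHR target list kept its call at the preset correlation (adjusted p = 4.74e-10) and stood at adjusted p = 0.109 with an estimated correlation.

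Limma called 4 genes in human AHR cells, all higher, and with the replicate block within genotype 5, adding Zfp36l1, which encodes an RNA-binding protein. In the fit without the block 528 genes had an unadjusted p under 0.05, against 909.7 expected. All TCDD arrays lay above all vehicle arrays in 608 genes and below in 704, 7.21% against 10% by chance. B3galnt2 and Tiparp lost their call without human AHR vehicle replicate 1 (adjusted p = 0.0616 for both) or 3 (0.0602 and 0.0618) or TCDD replicate 2 (0.06 for both), and Tiparp also without TCDD replicate 1 (0.054) or 3 (0.0525). Cyp1a1 (0.0652 to 0.374) and Rab30 (0.0746 to 0.429) lost theirs when any single one of the 6 human AHR arrays was left out. The same held for wild type vehicle replicate 1 or 3 or wild type TCDD replicate 1, and for Cyp1a1 also wild type vehicle replicate 2. Without wild type TCDD replicate 2 the number of genes called was 6, without the intensity trend it was 2, with every probe set tested it was 2 (Cyp1a1 and Rab30 at adjusted p = 0.0584 each), and with the mean over the probe sets of a gene it was 1. The ribosomal list lost its call without human AHR vehicle replicate 1 (0.544) or 2 (0.159) or TCDD replicate 2 (0.569) or 3 (0.0762). The proteasome list lost it without vehicle replicate 1 (0.367) or 3 (0.0532) or TCDD replicate 2 (0.423) or 3 (0.0525). The oxidative phosphorylation list lost it without vehicle replicate 2 (0.692) or 3 (0.0832) or TCDD replicate 1 (0.247), 2 (0.0712) or 3 (0.101). With no offset these lists stood at adjusted p = 0.0565 each, and with the mean over probe sets at 0.348, 0.573 and 0.253.

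**Figure D2:**
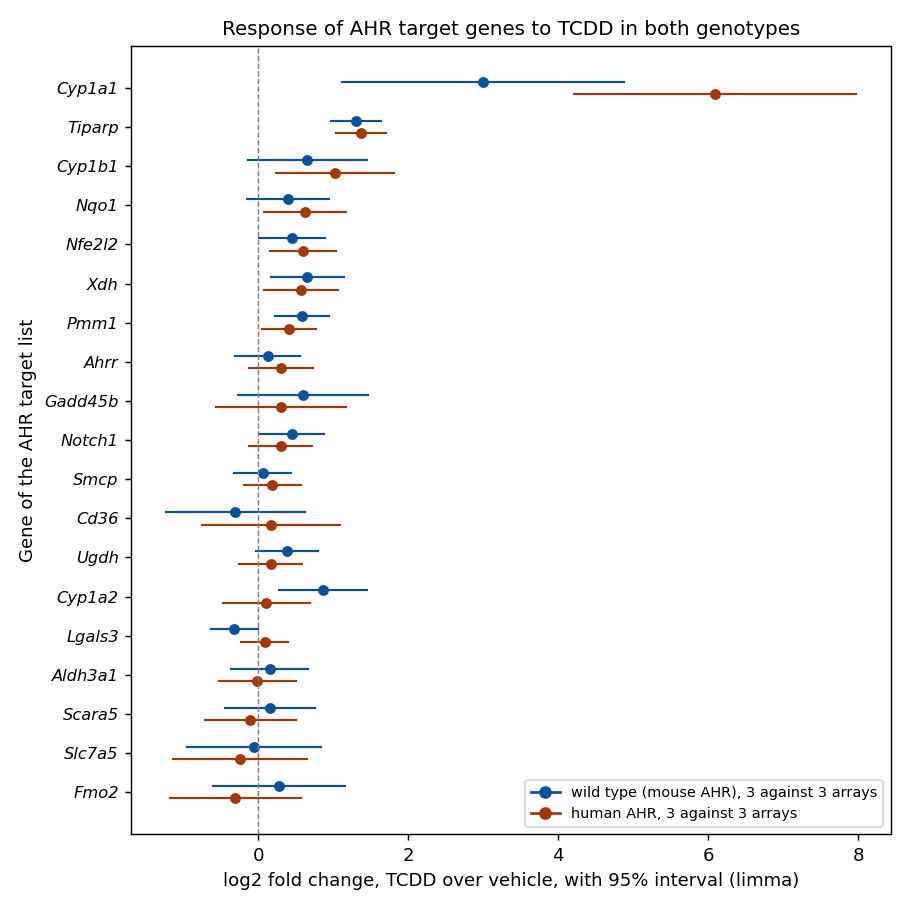
Log2 fold change of TCDD over vehicle, with its 95% interval from limma, for the 19 measured AHR target genes in wild type and in human AHR hepatocytes, 3 against 3 arrays each. Cyp1a1 lay at 3.00 in wild type and 6.09 in human AHR, and Tiparp at 1.30 and 1.37.

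Tiparp was the gene called in both genotypes, higher in each, against 0.00022 genes expected by independence (Fisher exact test, one-sided, p = 0.00022). B3galnt2 stood at 0.91 (adjusted p = 0.371) and Rab30 at 1.05 (adjusted p = 0.966) in wild type cells. Across all genes, which are not independent replicates, the log2 changes of the genotypes correlated with Pearson r = 0.086 and Spearman rho = 0.0483, and across the 10920 brighter genes with r = 0.168 and rho = 0.0905. At an unadjusted p under 0.05 in both, 66 genes were found, and 42 of them moved in the same direction, 33 up and 9 down, against 10.95 expected by independence. The rest of the 66 moved in opposite directions. Both comparisons share the estimate of each gene's spread, so independence is not what unchanged genes would give. The Tiparp call in wild type cells ended when any single human AHR array, wild type vehicle replicate 2 or 3, or wild type TCDD replicate 1 or 2 was left out. The shared count was then 0. With the replicate block within genotype the gene called in both was Rab30 and not Tiparp, which stood at adjusted p = 0.102 in wild type cells.

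Whether the receptors gave different responses was tested on the difference of the TCDD effects. Cyp1a1 had a response larger by 3.09 on the log2 scale in human AHR cells (standard error 1.23, 95% confidence interval 0.43 to 5.75, adjusted p = 0.998, and 0.443 adjusted over the list alone). For Cyp1a2 the difference was -0.76 (95% confidence interval -1.58 to 0.07), and for Tiparp 0.07 (-0.40 to 0.54). Genes of cholesterol synthesis differed as a group, with 17 of 20 members positive and a median difference of 0.37 (camera adjusted p = 0.00184, and adjusted p = 0.916 with an estimated correlation), from a median of -0.26 in wild type and of 0.02 in human AHR cells. Fdps stood at 0.81, Fdft1, the squalene synthase, at 0.72, and Dhcr7 at 0.64. Relative to the same wild type vehicle arrays, the list also had a median of -0.30 in human AHR vehicle arrays. The wild type TCDD effect, this difference and the genotype contrast under vehicle share the wild type vehicle arrays, so a shift in those arrays would enter each of them. Oxidative phosphorylation genes differed as well, with 21 of 24 positive and a median of 0.12 (adjusted p = 0.00194, and adjusted p = 0.916 with an estimated correlation), among them the complex I genes Ndufb3 at 0.34 and Ndufa9 at 0.29. With arrays shifted to the same median this list's median was 0.26, while the median of all genes moved from -0.04 to 0.10. In each list 0 members passed, over all genes or adjusted over the list alone, and the AHR target list was not called (adjusted p = 0.594), its mean at 0.12 and its median at -0.08.

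Limma called 0 genes for the difference, with 572 at an unadjusted p under 0.05 against 909.7 expected, and SAM was not run on it. Without wild type TCDD replicate 2, the array with the high Cyp1a1 signal, the Cyp1a1 difference was 4.61 (adjusted p = 0.000176) and 1 gene was called, and without both Xist-high arrays it was 4.59 (adjusted p = 0.00098). Removing an array that stands out by its own Cyp1a1 raises this difference and narrows its spread by construction. These adjusted p values are therefore no test of it. The cholesterol list lost its call without human AHR vehicle replicate 2 (adjusted p = 0.174), human AHR TCDD replicate 1 (0.0636) or wild type vehicle replicate 2 (0.0509), and the oxidative phosphorylation list without human AHR vehicle replicate 2 (0.137), wild type vehicle replicate 3 (0.0558) or wild type TCDD replicate 1 (0.147).

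The last comparison sets the genotypes side by side under vehicle. It shares its 3 wild type vehicle arrays with the wild type TCDD comparison, so lists called in the same direction in both are not separate findings. The Gapdh and Actb ratios of RNA integrity differ along with genotype in it, and whether they bear on the changes below was not tested. Cyp1a2, at 591 ± 154 in wild type, was at 2975 ± 391 in human AHR cells (SD, n = 3), a 5.01-fold higher signal (log2 2.32, standard error 0.27, 95% confidence interval 1.74 to 2.91, adjusted p = 0.0169), higher in 3 of 3 arrays. Markers of macrophages and Kupffer cells were higher as a group, with 18 of 19 positive and a median log2 difference of 1.07 (camera adjusted p = 1.18e-10, and adjusted p = 0.603 with an estimated correlation). Of these, 0 passed over all genes and 6 adjusted over the list alone. They were Vsig4 at 1.53, a complement receptor, C1qb at 1.90, a complement component, Clec4f at 1.13, a lectin of Kupffer cells, Ctss at 2.15, a protease, Laptm5 and Lyz2. Their signals were low, with Ctss at 18.0 in wild type and 167 in human AHR arrays and Vsig4 at 4.33 and 49.0. The size of these changes depended on the offset. Between an offset of 50 and none, Vsig4 lay from 0.81 to 3.28, Clec4f from 0.58 to 2.51, C1qb from 1.23 to 3.21 and Ctss from 1.46 to 3.39. Relative to the wild type vehicle mean, the mean of the macrophage markers lay at 0.0914, 1.37 and 1.78 in human AHR vehicle replicates 1, 2 and 3, so the difference lay in replicates 2 and 3.

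In the same contrast, and so along with the macrophage markers, genes of cholesterol synthesis were lower (18 of 20, median -0.30, adjusted p = 2.19e-06, and adjusted p = 0.603 with an estimated correlation), with Mvd, the mevalonate diphosphate decarboxylase, at -0.72 and Fdps at -0.76. Genes of fatty acid oxidation were lower (17 of 22, median -0.19, adjusted p = 0.00696, and adjusted p = 0.603 with an estimated correlation), with Cyp4a14, a fatty acid hydroxylase, at -1.43 and Cpt1a, which brings fatty acids into mitochondria, at -0.44. Oxidative phosphorylation genes were lower (21 of 24, median -0.08, adjusted p = 0.00196, and adjusted p = 0.603 with an estimated correlation), with Ndufb3 at -0.27, and the median was -0.14 with arrays shifted to the same median. Genes of the unfolded protein response were higher (22 of 24, median 0.26, adjusted p = 0.000304, and adjusted p = 0.625 with an estimated correlation), with the chaperone Calr at 0.37. Immediate early genes were higher (20 of 24, median 0.29, adjusted p = 0.00461, and adjusted p = 0.613 with an estimated correlation), with the transcription factors Egr1 at 0.73 and Fosb at 0.66. AHR targets were higher (11 of 19, median 0.17, adjusted p = 0.0394, and adjusted p = 0.603 with an estimated correlation), with 1 gene, Cyp1a2, passing over all genes and 1 adjusted over the list alone. With arrays shifted to the same median the AHR target median was 0.11, and the median of all genes moved from 0.03 to -0.03. In the other lists of this paragraph 0 members passed, over all genes or adjusted over the list alone.

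Limma called 1 gene between genotypes under vehicle, and 770 had an unadjusted p under 0.05 against 909.7 expected. Human AHR arrays lay above all wild type arrays in 1140 genes and below in 802, 10.7% against 10% by chance. Cyp1a2 lost its call without human AHR vehicle replicate 1 (adjusted p = 0.0691), 2 (0.161) or 3 (0.0905), human AHR TCDD replicate 1 (0.0502) or wild type vehicle replicate 2 (0.123) or 3 (0.137), and without both Xist-high arrays (0.0512) or the intensity trend (0.0593). Without human AHR vehicle replicate 2 the lists of fatty acid oxidation (0.0579), unfolded protein response (0.0579), immediate early genes (0.0598), oxidative phosphorylation (0.0734) and AHR targets (0.0579) lost their calls. Without wild type vehicle replicate 2 those of fatty acid oxidation (0.1) and immediate early genes (0.307) did, the latter also without both Xist-high arrays (0.096). The AHR target list also lost its call without human AHR vehicle replicate 1 (0.0705) or 3 (0.0915), human AHR TCDD replicate 2 (0.0501) or 3 (0.0563) or wild type vehicle replicate 3 (0.133).

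**Figure D3:**
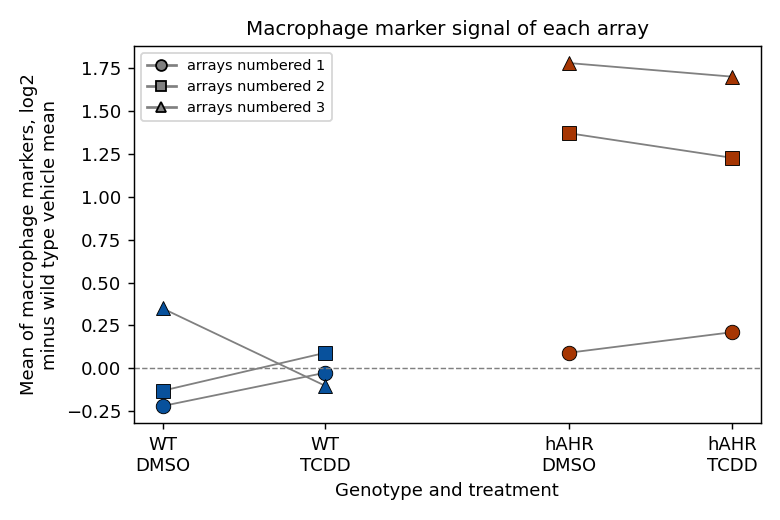
Mean of the 19 macrophage and Kupffer cell markers in each array, log2 relative to the wild type vehicle mean, for wild type (WT) and human AHR (hAHR) arrays under vehicle and TCDD, with lines joining arrays of the same number. Human AHR vehicle arrays lay at 0.0914, 1.37 and 1.78, and wild type arrays between -0.219 and 0.35.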

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

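All tests of uneven Cyp1a1 in this part were chosen only after the result was seen, while the splits of the arrays were planned. Cyp1a1 in wild type TCDD arrays was 26.5-fold higher in replicate 2 than in the mean of replicates 1 and 3, at 111, 5.53 and 2.87 times the vehicle mean in replicates 2, 1 and 3. Untreated cells in replicates 1 and 3 are argued against, because the other 3 genes called in human AHR cells, Tiparp, B3galnt2 and Rab30, lay 0.9881 above vehicle on the log2 scale in these arrays (1.30 in replicate 2, SD of the vehicle arrays 0.0668). Scaling of the arrays, which keeps the order of genes within each, is argued against too, since the log2 difference of Cyp1a1 was 4.57 as reported and 4.627 after quantile normalization (SD of the other brighter genes 0.571), which moved those genes by a median of 0.0528. The animal or culture of replicate 2 may be the source and cannot be told apart from a chance difference, as only 1 array treated with TCDD carried the high Xist signal, and no biological explanation was tested. Without that array the Cyp1a1 difference between genotypes was 4.61 (adjusted p = 0.000176), over a range of adjusted p from 0.000176 to 1 across settings. Since the array stands out by its own Cyp1a1, its removal raises the difference by construction, and that adjusted p does not test it.

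Xist read 3085 in wild type vehicle replicate 2 and 2952 in wild type TCDD replicate 2. It was fitted with the other genes, while its list, of sex chromosome transcripts, was not tested as a list.

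The TCDD effect on cholesterol synthesis genes differed between genotypes in a test of the difference itself (camera adjusted p = 0.00184, but adjusted p = 0.916 with an estimated correlation and 0.981 with fry). That test includes the wild type vehicle arrays, relative to which human AHR vehicle arrays were also lower (median -0.30).

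The TCDD effect on oxidative phosphorylation genes differed between genotypes in the same test (camera adjusted p = 0.00194, but adjusted p = 0.916 with an estimated correlation and 0.981 with fry).

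Splitting the 6 arrays of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. For TCDD in wild type cells the real split called 1 gene, 3 of the splits called as many, and the highest other called 422. That split set wild type vehicle replicate 1 and wild type TCDD replicates 1 and 3 against the rest, so the wild type arrays hold a structure that does not follow the treatment. For TCDD in human AHR cells the real split called 4 genes and the highest other 1, and among the 4 splits that part all same-numbered pairs the highest other called 0, while the replicate block within genotype called 5. For the genotypes under vehicle the real split called 1 gene and the highest other 0, so 1 of the splits reached it. For the difference of the TCDD effect the real count was 0, which all 100 of 100 drawn assignments of treatment reach whatever the data, so these splits decide nothing, and the highest of them called 786.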

How the results depend on the processing

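The cause of each change below was not tested. TCDD in wild type cells called 1 gene as reported, and 0 with arrays shifted to the same median, 0 without the trend, 1 with every probe set tested (2 probe sets of Tiparp), 0 with a replicate block over all 12 arrays, 0 from only its 6 arrays, 0 with SAM and 0 with both wild type replicate 2 arrays left out, with leave-one-out counts of 0 to 1. TCDD in human AHR cells called 4 genes, and 2 without the trend, 2 with every probe set tested (3 probe sets of B3galnt2 and Tiparp, with Cyp1a1 and Rab30 at adjusted p = 0.0584 each) and 1 with the mean over the probe sets of a gene, with leave-one-out counts of 0 (without human AHR vehicle replicate 1 or 3 or TCDD replicate 2) to 6 (without wild type TCDD replicate 2). It called 6 with array weights, from only its 6 arrays or with both wild type replicate 2 arrays left out. With offset 50, quantile normalization or the shared median it called 5. The difference called 0 genes, and 1 (Cyp1a1) with both wild type replicate 2 arrays left out, with leave-one-out counts of 0 to 1. Human AHR against wild type under vehicle called 1 gene, and 2 with offset 50, 0 without the trend, 2 with array weights, 2 with the mean over probe sets, 2 with every probe set tested (3 probe sets of Adi1 and Cyp1a2), 2 without probe sets ending in _x_at or _s_at, 0 with a replicate block over all 12 arrays and 2 with SAM, with leave-one-out counts of 0 to 2 (Plek and Tmem18, without human AHR vehicle replicate 1). With both wild type replicate 2 arrays left out it called 1 gene, Cyp2b10 in place of Cyp1a2. The overlap held 1 gene, and 0 with the shared median, without the trend, with a replicate block over all 12 arrays, from only the 6 arrays or with both wild type replicate 2 arrays left out, 1 with every probe set tested (2 probe sets of Tiparp) and 42 at an unadjusted p under 0.05, with leave-one-out counts of 0 to 1. With the replicate block within genotype the shared gene was Rab30 in place of Tiparp. Lists called fell from 5 to 1 in wild type with an estimated correlation or fry (leave-one-out 4 to 8). In human AHR cells they fell from 5 to 1 with either, and to 2 with no offset or the mean over probe sets (leave-one-out 1 to 5). For the difference they went from 2 to 0 with either, and to 5 with both wild type replicate 2 arrays left out (leave-one-out 0 to 7). Under vehicle they went from 7 to 0 with either (leave-one-out 2 to 10). Same-numbered wild type arrays correlated unevenly in their deviations from the group means (0.047 to 0.51, other numbers up to 0.28), not every array best with its own number, and were not taken as pairs. The replicate block within genotype called 1 gene in wild type (Rab30, with Tiparp at adjusted p = 0.102), 5 in human AHR cells (the 4 reported and Zfp36l1), 0 for the difference and 6, 6 and 3 lists, adding NRF2 targets in human AHR cells, fatty acid oxidation in wild type and the unfolded protein response for the difference. It ended no list call at the preset correlation and changed no other call of human AHR cells. With an estimated correlation in that fit, none of the lists called at the preset correlation was called. The AHR targets stood at adjusted p = 0.263 in wild type and 0.109 in human AHR cells. Over all 12 arrays the block called 3 genes in human AHR cells, without Cyp1a1 (adjusted p = 0.115), and 4, 5, 2 and 8 lists. Shifting arrays to the same median moved the median of all genes in wild type from 0.03 to -0.09, and no median of a called list changed sign with this, quantile normalization or a rescaling to 500, though some moved by a factor over 1.5, such as oxidative phosphorylation in wild type from -0.05 to -0.17 with the shared median. The rescaling to 500 kept the counts of genes at 1, 4, 0 and 1. Named genes gave 143 values, 6 of them called, and 3780 comparisons with other settings, with 60 called values losing and 2 gaining a call, 0 reversed and 91 crossing 0 without a call. Adjusted p ranged over settings from 0.0048 to 0.986 for Tiparp in wild type, and in human AHR cells from 3.72e-08 to 0.374 for Cyp1a1, 0.000359 to 0.843 for Rab30, 0.00166 to 0.524 for B3galnt2 and 0.000408 to 0.0618 for Tiparp, and from 0.000281 to 0.161 for Cyp1a2 under vehicle.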

Other observations

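The comparisons over both genotypes or both treatments in this part, and the tests of neighbouring genes against permuted positions and of the hepatocyte share, were chosen only after the result was seen. With TCDD taken over both genotypes, Tiparp rose by 1.34 on the log2 scale (standard error 0.11, adjusted p = 0.000241), Rab30 by 1.34 (adjusted p = 0.0109), B3galnt2 by 1.18 (adjusted p = 0.000495) and Cyp1a1 by 4.54 (adjusted p = 0.0233). Wild type arrays were not taken as pairs, and with a replicate block within the human AHR arrays only, 3 genes were called, with B3galnt2 and Tiparp at adjusted p = 0.00189 each, Rab30 at 0.0393 and Cyp1a1 at 0.149. A replicate block in both genotypes called 6 genes, adding Xdh at 0.61, the xanthine dehydrogenase (adjusted p = 0.0181), and Rgs2 at -1.79, a regulator of G-protein signalling (adjusted p = 0.0181). These additions rest on the wild type numbers, since with the block in human AHR arrays only both stood at adjusted p = 0.968. Exchanging treatments within the 6 same-numbered pairs gives 32 assignments, of which 1, the real one with 6 genes, called as many, and the highest other called 0. This cannot exclude chance for that count, because the contrast was chosen after the data were seen. The exchange also relies on wild type pairs, which the wild type values bear out unevenly. Deviations from the group means correlated with r = 0.507 for number 2, whose arrays both had the high Xist signal. They correlated with 0.251 for number 1, against 0.282 between vehicle 1 and TCDD 3, and with 0.0475 for number 3.

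With genotype averaged over treatments and 12 arrays taken as independent, limma called 4 genes and 970 had an unadjusted p under 0.05. Cyp1a2 was higher in human AHR arrays by 1.95 (adjusted p = 0.00237). Tmem18 (-2.20, adjusted p = 0.0066), Eif4e2, a cap-binding protein (-0.86, adjusted p = 0.00237), and Atg16l1, a gene of autophagy (-0.72, adjusted p = 0.0066), were lower. Same-numbered human AHR arrays are not independent, and on the mean of same-numbered arrays, 3 against 3, limma called 2 genes, Tmem18 (adjusted p = 0.00955) and Cyp1a2 (0.0144), with Eif4e2 at 0.313 and Atg16l1 at 0.572. Over the arrays without both wild type replicate 2 arrays 8 genes were called.

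Eif4e2 and Atg16l1 lie near each other on a chromosome, and in a window of 25 neighbouring tested genes around them 5 genes had p under 0.01, with Gigyf2 at -0.69, Dgkd at -0.60 and Usp40 at -0.98, all lower in all 6 human AHR arrays than in the 6 wild type arrays. As a hypothesis, DNA segments linked to the alleles of the human AHR line may lower such neighbours, and permuted gene positions gave as high a count in a share of 0.0408 (10000 permutations, median 3), and of 0.0029 on the mean of same-numbered arrays, where the same 5 genes formed the highest window. A difference between cultures or days rather than DNA stays open as well, since replicate 2 against 1 and 3 among the human AHR arrays gave a window of 6 (759 genes at p under 0.01 against 223 for genotype, and 5 with as many genes). On the chromosome of Ahr the highest window held 4 genes, Dtd2 (-1.35), Arhgap5 (-0.51), Ap4s1 and Heatr5a, and Ahr lay 10 tested genes away. Permuted positions matched that count somewhere on the autosomes in a share of 0.473, which does not test this chromosome by itself. On it 15 of 622 tested genes had p under 0.01, 10 of them lower in human AHR, against 223 of 17400 over all autosomes. Whether that is an excess was not tested. Genotype and day of culture are not separated by the design.

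Macrophage and Kupffer cell markers were higher in human AHR arrays, with medians of 1.07 under vehicle and 1.04 under TCDD. A lower share of hepatocytes, with every other cell type raised alike, is argued against for these vehicle arrays. The smallest gap to endothelial (0.129), stellate (0.158) or cholangiocyte (0.0618) medians was 0.9115 (standard error 0.324). That standard error comes from resampling the markers of each list, so it does not measure the spread between cultures. More macrophages in the human AHR cultures remains a hypothesis that the values fit, with an exact permutation p of 0.01082 (two-sided) for genotype over 12 arrays. The list was singled out by its difference in the vehicle arrays, which are among these 12, so this p is not a separate test. However, human AHR arrays of a number moved together (within 0.143), while wild type arrays of a number differed by up to 0.451. By 6 cultures the exact permutation p is 0.1, the smallest that design allows. That count of cultures also joins same-numbered wild type arrays, which were not taken as pairs. Human AHR replicate 1 lay at 0.0914 and 0.211, so the difference may belong to single cultures, and a biological effect of the genotype on these cells was not tested apart from it. The brightest marker, Cd68, stood at 2392 in wild type and 2729 in human AHR vehicle arrays and so was expressed in cultures of both genotypes, Ctss went from 18.0 to 167, and no gene of the list is in another list.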
